A study of Mus musculus with 6 samples.

How the data were processed

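RNA-seq libraries of CD8+ T cells collected from mouse spleen were compared between 3 control libraries (Cd4cre) and 3 knockout (KO) libraries (Cd4cre with floxed Glut10, the protein name of Slc2a10). Per the labels' protocols, cells were frozen, RNA was taken up in Trizol, libraries were made with an NEBNext Ultra kit and sequencing ran on a NovaSeq instrument. The submitters' processing notes name HISAT2 version 2, Bowtie2 2.2.3, HTSeq 0.6.0 and the build mm8, with no role or order. The step from reads to FPKM, the strand setting and the annotation were not given in the sources used here.

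The deposited values were FPKM (fragments per kilobase of gene, scaled to the depth of the library), 1 value per gene and library, for 35458 Ensembl gene identifiers. That the unit is FPKM was read from the values themselves, since per the labels no unit is stated for the authors' values. Of the identifiers, 35313 matched the GENCODE M21 annotation, from which symbols, gene types, exon lengths and relative positions of genes were taken. Because the notes name another build, no coordinates are given.

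No read counts were analysed here. Multiplied by the summed exon length of the gene, the low FPKM values fell on whole multiples of 1 step per library. Among values of under 200 implied reads, 92.1% to 93.4% lay within 0.02 read of a whole number. The step gives the total by which each library was divided, 11840600, 15020100 and 15036300 fragments in control 1, 2 and 3 and 3420290, 14683400 and 3004540 in KO 1, 2 and 3. Implied reads summed over genes came to 8.25% to 12.3% more than these totals, so the depths are approximate. A floor of 3 reads in a gene of 1 kb was 0.253, 0.200 and 0.200 FPKM in the controls and 0.877, 0.204 and 0.998 FPKM in the KO libraries. Floors and intervals cover counting error only. No 2 libraries agreed within sampling noise, with a chi-square per gene of 16.4 to 195 between libraries of 1 group.

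The tests, their samples, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The plan named a count model for the case that counts were given and limma for normalized values. As the values were FPKM, limma was used. Genes with at least 1 FPKM in at least 3 libraries were kept (13956 genes) and log2(FPKM + 1) was tested with limma 3.58.1 (R 4.3.3), with an intensity trend on the variance, group as the only term and Benjamini-Hochberg adjustment at 0.05. A log2 difference is on the log2(FPKM + 1) scale throughout, which understates changes of low genes. Errors of means are SD over 3 libraries. The smallest p that an exact permutation test of 3 against 3 libraries can give is 0.1, so none was used for single genes.

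In all, 32 gene lists were fixed, holding 685 entries, of which 682 matched by symbol, 1 by a table of synonyms and 2 were absent. A total of 2 genes stood in more than 1 list. Lists with at least 5 tested members were tested with camera at its preset correlation of 0.01, adjusted over 31 lists, with camera's estimated correlation and fry beside it. For each list, the number of genes past the threshold is also given adjusted over the list alone. Named genes were Slc2a10, up to 12 genes in each direction with the largest change among those past the threshold, and from each list up to 4 members past the threshold or, where none passed, at most 2 by smallest p, as values only. Not all genes that this rule named are reported here. Immunoglobulin and T cell receptor segments, sex-linked markers and clone-named gene models were left out of the ranking. As 0 genes passed, the ranking named none, and genes outside the rule were chosen after their values were seen.

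The procedure was tested on simulated data for the KO against control comparison. With reads drawn for 13927 genes at the implied totals and a dispersion of 0.1, 2% of the genes changed 2-fold and 64% of those changed 4-fold were recovered, and 6 unchanged genes were called. With the spread that each of the 13956 tested genes had in these libraries, 0% and 20% were recovered, and 2 unchanged genes were called.

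Other settings planned before testing were a pseudocount of 0.1, no low-value filter, quantile normalization, the replicate number as a block, each library left out in turn, removal of antigen receptor segments and a log2 threshold of 1. Planned count models were not run. Added after the data were seen were fits without control 2 and 3, fits without KO 1 and 3, a covariate for the neutrophil list, protein-coding genes only and limma-voom on implied reads. For the share of gene models with a read, each library was thinned to 3314529 implied reads, the lowest sum over genes. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.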

Results

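CD8+ T cells from mouse spleen were profiled by RNA-seq in 3 control libraries from Cd4cre mice and 3 KO libraries from mice that carried Cd4cre with floxed alleles of Glut10. Cd4cre drives Cre recombinase in developing T cells, including those that become CD8+ cells. Glut10 is the product of Slc2a10, a member of the facilitative hexose transporter family. The comparison asks how the transcriptome of CD8+ T cells differs when this transporter is deleted. The labels do not say whether the libraries of a group came from separate mice. The limma p-values therefore measure the spread between these libraries, which may be technical. At camera's preset correlation, genes of a list are treated as varying almost independently, so those camera p-values do not measure this spread. Sex is not given in the labels either. The title of the series mentions lymphoma, and the labels do not say whether the mice carried tumours.

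The totals implied by the FPKM values were 11840600, 15020100 and 15036300 fragments in control 1, 2 and 3, and 3420290, 14683400 and 3004540 in KO 1, 2 and 3. KO 1 and KO 3 had the lowest totals and the most genes with at least 1 FPKM, 18934 and 19268, against 13713, 12559 and 12850 in the controls and 12200 in KO 2. After every library was thinned to 1 common total, 75.5% and 77.2% of all 35458 gene models had a read in KO 1 and KO 3, against 51.2% to 59.9% in the other 4 libraries. Over 905 olfactory and vomeronasal receptor genes, which serve in sensory neurons, the shares were 62.4% and 66.5% in KO 1 and KO 3, 10.2% in KO 2, and 24.97%, 13.3% and 17.8% in control 1, 2 and 3. The first principal component, with 64.0% of the variance, placed KO 1 at 102 and KO 3 at 111, and the other 4 libraries between -69.5 and -20.8. Control 1 correlated more closely with KO 2 (Pearson r of log2 values across genes, 0.967) than with control 2 (0.931) or control 3 (0.926). Genes are not independent replicates, and these r describe the libraries only.

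**Figure D1:**
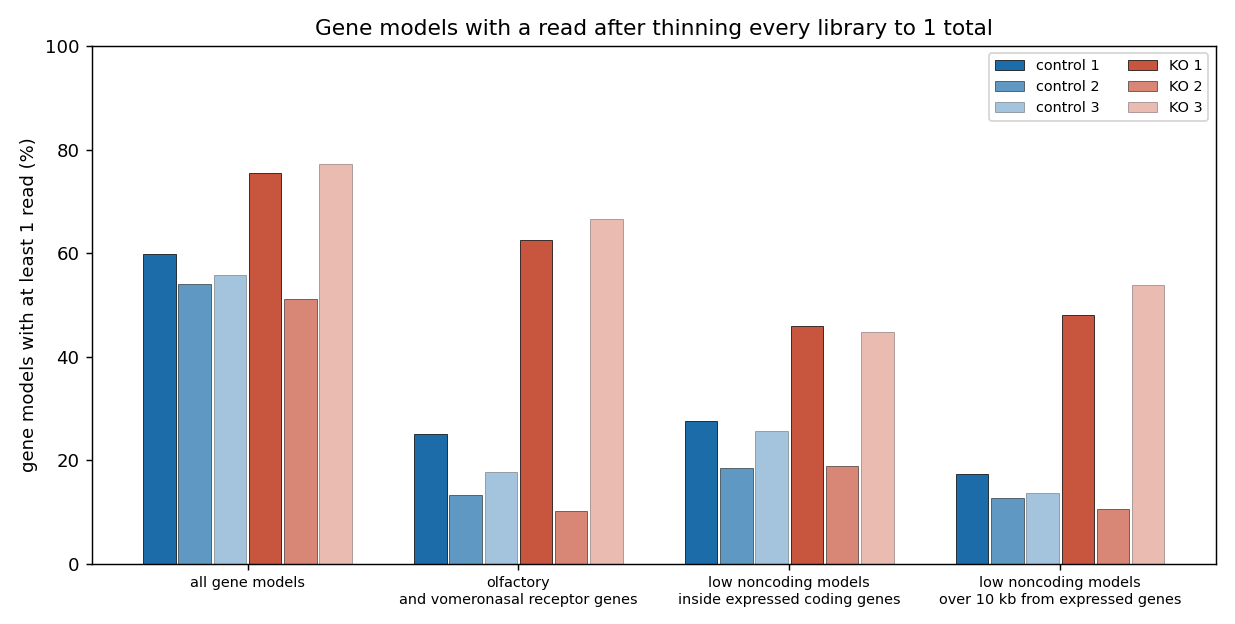
Share of gene models with at least 1 read (y axis, percent) in each of the 6 libraries after thinning to a common number of implied reads, for all gene models, sensory receptor genes and low noncoding models inside or over 10 kb away from expressed genes. KO 1 and KO 3 stand above the other 4 libraries in each set, with 62.4% and 66.5% of the sensory receptor genes against at most 24.97%.

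Slc2a10 (ENSMUSG00000027661), the targeted gene, was close to the limit of detection in the control cells and had no reads in the KO cells. It measured 0.0946, 0.0373 and 0.0373 FPKM in control 1, 2 and 3, or 4, 2 and 2 implied reads, and 0 FPKM in KO 1, 2 and 3. The floors of 3 reads for this gene were 0.0710, 0.0559 and 0.0559 FPKM in the controls and 0.246, 0.0572 and 0.280 FPKM in KO 1, 2 and 3. Pooled, the controls held 8 reads of 41897000 and the KO libraries 0 reads of 21108230, where 4.03 would be found at the control rate. An exact two-sided binomial test of these pooled reads gave p = 0.0584, which compares these libraries, not the genotypes. The values cover the whole gene, and the deleted exon is not given in the labels. At this depth a loss of Slc2a10 was not detectable beyond counting error.

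Pdk1 (ENSMUSG00000006494), a kinase that inhibits pyruvate dehydrogenase and so limits entry of pyruvate into the TCA cycle, was the autosomal gene with the smallest p. It measured 5.78 ± 0.345 FPKM in the controls and 26.9 ± 4.88 in the KO cells (SD, n = 3 each), a log2 difference of 2.03 (SE 0.23), with every KO library above every control. Csf2rb (ENSMUSG00000071713), the common beta chain of the receptors for GM-CSF, IL-3 and IL-5, measured 68.0 ± 7.98 FPKM in the controls and 22.1 ± 2.59 in the KO cells, a log2 difference of -1.58 (SE 0.19). Its close relative Csf2rb2 measured 31.3 ± 5.46 and 9.51 ± 2.15 FPKM. Any reads shared by this pair of similar genes would leave both values uncertain, and such reads were not measured. Vim, the intermediate filament vimentin, measured 179 ± 12.6 and 80.5 ± 14.0 FPKM. Csf2rb, Csf2rb2 and Vim were chosen after their values were seen, and none of these 4 genes passed the threshold. Csf2rb measured 72.4, 58.8 and 72.8 FPKM in control 1, 2 and 3. Whether RNA of non-T cells contributes to Csf2rb, Csf2rb2 or Vim was not tested. Slc2a8, Ldha, Cd8a, Lef1, Gzmb, Top2a, S100a8, S100a9 and Hbb-bs, given below, were also chosen after their values were seen.

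Of 13956 genes tested, 0 passed limma at an adjusted p of 0.05, and the smallest limma adjusted p, 0.151, was that of Xist. The limma adjusted p was 0.310 for Pdk1, 0.327 for Csf2rb and 0.417 for Csf2rb2 and Vim. At an unadjusted p under 0.05 there were 1646 genes, 744 higher and 902 lower in the KO cells, where 697.8 are due by chance. Groups did not overlap for 2252 genes (935 higher, 1317 lower), or 16.1%, where chance gives 10%. Both chance values are averages over groupings. As genes vary together, 1 grouping can lie far from them, and neither number was computed for other splits, so no excess was tested. limma-voom on the implied reads, added after the data were seen, also called 0 of 16247 genes, with 1349 at an unadjusted p under 0.05. The median log2 difference of all tested genes was 0.10, and -0.12 after quantile normalization. Estimates were higher in KO for 7941 genes and lower for 6015, and after quantile normalization higher for 5890 and lower for 8066. Without control 1, 363 genes passed (146 higher, 217 lower), and without KO 2, 1821 passed (1687 higher, 134 lower), of which 37 were shared. Fits without control 2 and 3 or without KO 1 and 3, added after the data were seen, leave 1 library in that group, which is assumed to vary like the libraries of the other group, so their p compare a single library and do not test the genotypes. For lists, the medians of those fits are given below without p, although some lists passed there, in either direction. Protein-coding genes made up 30.2% of the 1687 higher genes without KO 2, against 77.6% of the genes tested. Pdk1 had a limma adjusted p of 0.0287 without control 1 and 0.00418 without KO 2, and Csf2rb 0.0357 and 0.0114. With control 2, control 3, KO 1 or KO 3 left out singly, both genes had a limma adjusted p of 0.708, 0.801, 0.723 and 0.736.

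Slc2a1, the main glucose transporter of activated T cells, measured 20.5 ± 3.90 FPKM in the controls and 10.99 ± 2.48 in the KO cells, and Slc2a6 13.6 ± 3.34 and 5.53 ± 1.70, with every KO library below every control for both. The log2 difference of Slc2a1 was -0.85, and -0.54 without KO 1 and 3. Slc2a8, another transporter of this family, measured 3.08 ± 0.549 and 4.05 ± 0.740 FPKM. Hk2, a hexokinase that traps glucose as glucose 6-phosphate, measured 14.2 ± 7.74 and 3.60 ± 1.29 FPKM, and its relative Hk3 78.9 ± 49.3 and 12.7 ± 3.77. G6pdx, which starts the pentose phosphate pathway, measured 83.1 ± 37.9 and 23.7 ± 3.67 FPKM, and Pgd, a later enzyme of that pathway, 184 ± 105 and 52.3 ± 21.8. Hk3, Hk2, G6pdx and Pgd were also higher in control 2 and 3, where neutrophil genes were high, than in control 1: Hk2 measured 6.52 FPKM in control 1 and 14.03 and 21.99 in control 2 and 3. The log2 differences of Hk3, Hk2, G6pdx and Pgd were -0.87, -0.75, -0.86 and -0.53 without control 2 and 3, against -2.29, -1.62, -1.66 and -1.67 with all libraries.

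No member of these lists passed the test over all genes. Of the 5 hexose transporters tested (Slc2a10 was not in the list), 3 had lower and 2 higher estimates, and 2 passed lower when adjusted over the list alone, Slc2a6 and Slc2a1. The list did not pass, with a median log2 difference of -0.85 (camera adjusted p = 0.0880), and the median was -0.43 without control 3, -0.28 without control 2 and 3 and -0.54 without KO 1 and 3. Of 25 glycolysis genes, 19 had lower and 6 higher estimates, 0 passed adjusted over the list alone, and the median was -0.35 (camera adjusted p = 0.00946, and adjusted p = 0.639 with an estimated correlation). Ldha, the lactate dehydrogenase of this list, measured 220 ± 71.1 and 238 ± 187 FPKM. Of 9 pentose phosphate genes, 7 had lower estimates, 1 passed lower adjusted over the list alone (G6pdx), and the median was -1.03 (camera adjusted p = 0.00233, and adjusted p = 0.639 with an estimated correlation). The glycolysis median was -0.11 without KO 3 (camera adjusted p = 0.0617), -0.19 without control 2, -0.16 without KO 1, -0.69 without KO 2 and 0.30 without KO 1 and 3 together. Without control 2 and 3 the medians were -0.21 for glycolysis and -0.27 for the pentose phosphate pathway, and without KO 1 and 3 that of the latter was -0.70.

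**Figure D2:**
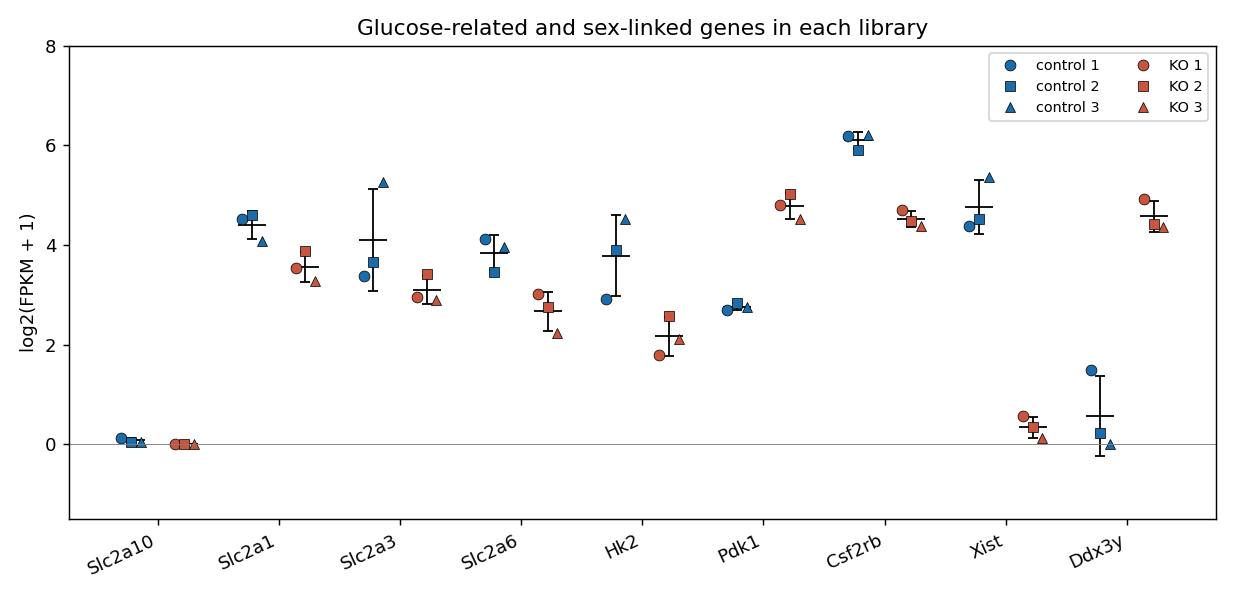
Level of 9 genes as log2(FPKM + 1) (y axis) in each library, with group mean and SD as bars. Pdk1 lies at 5.44 to 6.13 FPKM in the controls and 22.04 to 31.8 in the KO libraries, Slc2a10 lies at or near 0 throughout, and Xist and Ddx3y separate the groups completely.

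Slc7a5, the large neutral amino acid transporter, measured 41.9 ± 7.41 FPKM in the controls and 15.8 ± 9.31 in the KO cells, and Slc7a11, the cystine transporter, 49.1 ± 33.9 and 5.86 ± 2.04. Xbp1, a transcription factor of the unfolded protein response, measured 65.2 ± 18.7 and 27.2 ± 3.57 FPKM, and Chac1, a glutathione-degrading target of the integrated stress response, 8.96 ± 5.17 and 0.960 ± 0.590. In control 1, where the mean of the neutrophil list was lower, Slc7a11 measured 12.6 FPKM against 54.8 and 79.8 in control 2 and 3. Chac1 measured 3.10 against 12.9 and 10.9. Their log2 differences were -1.04 and -1.11 without control 2 and 3, against -2.57 and -2.21 with all libraries. That of Xbp1 was -0.80 without control 2 and 3 against -1.20, and that of Slc7a5 -0.64 without KO 1 and 3 against -1.48. In 3 of 11 neutrophil and 4 of 15 macrophage markers, every KO library lay below control 1 too. RNA of non-T cells may therefore remain in the differences without control 2 and 3, here and above. Of 19 integrated stress and unfolded protein response genes, 17 had lower estimates, 7 with every KO library below every control.

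The stress response list had a median of -0.71 (camera adjusted p = 3.10e-06, and adjusted p = 0.639 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. Its median was -0.46 without control 2, -0.37 without control 2 and 3 and -0.53 without KO 1 and 3. Of 22 genes of amino acid transport and one-carbon metabolism, 14 had lower and 8 higher estimates, and 0 passed adjusted over the list alone. The median was -0.19 (camera adjusted p = 0.0378, and adjusted p = 0.664 with an estimated correlation). That call was lost without control 2 (median -0.16, camera adjusted p = 0.160), without KO 3 (median 0.03, camera adjusted p = 0.334) and among protein-coding genes alone (camera adjusted p = 0.129). The list median was -0.34 without control 2 and 3 and 0.25 without KO 1 and 3. Its median was -0.44 without KO 2 and -0.41 after quantile normalization.

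Of the 15 genes tested in the hypoxia response list, which holds Pdk1, 11 had lower estimates. Its median was -0.49 (camera adjusted p = 0.0152, and adjusted p = 0.639 with an estimated correlation), and 1 gene, Pdk1, passed higher adjusted over the list alone. Bhlhe40 of this list, a transcriptional repressor, measured 38.9 ± 5.34 FPKM in the controls and 18.4 ± 8.19 in the KO cells, a log2 difference of -1.14, and -0.60 without KO 1 and 3. The call was lost without control 2 (camera adjusted p = 0.0594), and the list median was -0.28 without control 3. That median was -0.21 without control 2 and 3 and -0.33 without KO 1 and 3.

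The TCA cycle (median -0.08, camera adjusted p = 0.148), fatty acid oxidation (median 0.07, mean 0.01, camera direction lower, adjusted p = 0.866), cholesterol and fatty acid synthesis (median -0.14, camera adjusted p = 0.0772), the nuclear-encoded respiratory chain (median 0.06, camera adjusted p = 0.866) and the mitochondrially encoded genes (median -0.46, camera adjusted p = 0.0578) did not pass. In each of these lists 0 members passed over all genes and 0 adjusted over the list alone. Examples were Dld at 32.9 ± 5.58 and 22.4 ± 6.81 FPKM, Cpt1a, the gatekeeper of mitochondrial fatty acid import, at 41.4 ± 6.32 and 24.5 ± 6.75, Dhcr7 at 5.46 ± 2.22 and 23.1 ± 13.02 (31.5, 8.08 and 29.6 in KO 1, 2 and 3), Cycs at 34.3 ± 11.2 and 20.8 ± 8.01, and mt-Nd5 at 1012 ± 213 and 590 ± 423. The log2 differences of Dld, Dhcr7, Cycs and mt-Nd5 were -0.12, 0.54, -0.17 and 0.03 without KO 1 and 3, against -0.56, 1.74, -0.72 and -1.09 with all libraries. camera passed the TCA cycle lower without control 3 (median -0.18, camera adjusted p = 0.0178) or KO 2 (median -0.15, camera adjusted p = 0.0261), while its median was 0.02 without control 1, -0.29 after quantile normalization and 0.08 without KO 1 and 3. The fatty acid oxidation median was 0.00 without control 3, 0.13 without control 2, 0.22 without KO 1 and -0.13 after quantile normalization. camera passed cholesterol and fatty acid synthesis lower without KO 2 (median -0.31, camera adjusted p = 0.0261), with a median of -0.06 without KO 3, -0.37 after quantile normalization and -0.04 without KO 1 and 3. Among fits with at least 2 libraries per group, it passed the respiratory chain higher without control 2 (median 0.24, camera adjusted p = 0.0103) or KO 1 (median 0.26, camera adjusted p = 0.00770). The respiratory chain median was -0.06 without control 3 and -0.04 after quantile normalization. With 1 library in a group it was also higher, at 0.13 without control 2 and 3 and 0.27 without KO 1 and 3. The mitochondrially encoded genes passed lower without control 3 (camera adjusted p = 0.0495) or KO 2 (median -0.68, camera adjusted p = 0.00661), while their median was -0.11 without KO 3, -0.18 without control 2 and 3 and 0.21 without KO 1 and 3.

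The mean log2(FPKM + 1) of the T cell core genes was 6.77, 5.34 and 5.09 in control 1, 2 and 3 and 6.69, 7.26 and 6.58 in KO 1, 2 and 3. Thy1 measured 84.4, 14.8 and 26.9 FPKM in control 1, 2 and 3 and 163, 197 and 111 in KO 1, 2 and 3. Cd3d, a chain of the T cell receptor complex, measured 153, 77.3 and 48.4 FPKM and 172, 288 and 216, and Cd8a 191, 30.3 and 31.8 FPKM and 101, 252 and 90.7. Dapl1, from the list of naive and memory genes, measured 17.7 ± 11.3 FPKM in the controls and 79.9 ± 6.93 in the KO cells, and Cxcr5 2.58 ± 1.37 and 7.77 ± 3.58. Lef1, a transcription factor of naive T cells, measured 49.1, 7.71 and 5.94 FPKM in control 1, 2 and 3 and 63.7, 47.2 and 63.6 in KO 1, 2 and 3. The log2 differences of Thy1, Cd3d, Dapl1 and Cxcr5 were 0.85, 0.52, 1.35 and 0.70 without control 2 and 3, against 2.199, 1.40, 2.27 and 1.28 with all libraries.

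All 18 T cell core genes had higher estimates, 7 of them with every KO library above every control, and the median was 1.21 (camera adjusted p = 5.22e-05, and adjusted p = 0.639 with an estimated correlation). Over all genes and adjusted over the list alone, 0 passed. Of 22 naive and memory genes, 20 had higher estimates and 1, Dapl1, passed higher adjusted over the list alone. Their median was 1.21 (camera adjusted p = 1.65e-04, and adjusted p = 0.639 with an estimated correlation). Without control 2 and 3 the medians were 0.13 for T cell core genes and 0.01 for naive and memory genes. The T cell core call was lost without KO 2 (camera adjusted p = 0.0930), and its median was 0.77 without control 3, while that of naive and memory genes was 0.81 without control 2.

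Ccl3 measured 178 ± 103 FPKM in the controls and 27.5 ± 9.98 in the KO cells, and Ccl4 42.0 ± 14.3 and 10.6 ± 5.43, both chemokines that activated CD8+ T cells and myeloid cells secrete. Ier3 measured 71.7 ± 60.5 and 13.7 ± 3.23 FPKM, and Fosl2, a subunit of the AP-1 transcription factor, 9.60 ± 5.84 and 1.78 ± 0.444. Ccl3, Ier3 and Fosl2 were also higher in control 2 and 3 than in control 1, at 274 and 192 against 69.1 FPKM, 140 and 50.1 against 24.9, and 11.8 and 14.05 against 2.99. Their log2 differences were -1.36, -0.84 and -0.53 without control 2 and 3, against -2.51, -1.98 and -1.73 with all libraries. The cytotoxic protease Gzmb measured 53.3, 81.0 and 26.7 FPKM in control 1, 2 and 3 and 6.80, 112 and 4.22 in KO 1, 2 and 3. The checkpoint receptor Havcr2 measured 5.93 ± 1.86 and 2.51 ± 1.35 FPKM, and Rgs16 6.95 ± 3.99 and 2.04 ± 0.919. Zbtb7b, the CD4 lineage factor, measured 17.1 ± 8.73 and 3.49 ± 1.03 FPKM, and Cd4 4.43 ± 1.66 and 1.61 ± 0.509. In control 1, 2 and 3, Rgs16 measured 3.07, 6.75 and 11.03 FPKM and Zbtb7b 8.47, 16.99 and 25.9, and their log2 differences were -0.47 and -1.10 without control 2 and 3, against -1.30 and -1.91.

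Of 27 activation and immediate early genes, 19 had lower estimates and the median was -0.25 (camera adjusted p = 0.00574, and adjusted p = 0.639 with an estimated correlation). The median was -0.42, -0.48 and -0.38 without control 3, KO 1 and KO 2, -0.40 after quantile normalization, -0.39 without control 2 and 3 and -0.14 without KO 1 and 3. The effector list (17 of 29 higher, median 0.13, mean -0.01, camera direction lower, adjusted p = 0.614), inhibitory receptors and exhaustion (median 0.08, mean -0.09, camera direction lower, adjusted p = 0.448) and CD4 and regulatory T cell markers (median 0.03, mean -0.27, camera direction lower, adjusted p = 0.300) did not pass. Adjusted over the list alone, 1 CD4 and regulatory T cell marker passed lower, Zbtb7b, and 0 genes of the other lists in this paragraph did. Over all genes, 0 passed. With 1 library left out, the effector median ranged from -0.18 without control 3 to 0.45 without control 1, that of exhaustion from -0.37 without KO 2 to 0.31 without KO 3, and that of CD4 and regulatory T cell markers from -0.27 without control 3 to 0.41 without KO 3. The 3 medians were -0.06, -0.15 and -0.24 after quantile normalization, -0.54, -0.28 and -0.53 without control 2 and 3, and 0.23, 0.57 and 0.18 without KO 1 and 3.

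Rps7, a ribosomal protein gene, measured 464 ± 99.2 FPKM in the controls and 904 ± 182 in the KO cells. Mki67, the proliferation marker, measured 19.6, 23.0 and 41.8 FPKM in control 1, 2 and 3 and 9.56, 33.2 and 4.86 in KO 1, 2 and 3, and Top2a 26.1, 22.3 and 32.2 FPKM and 13.4, 51.5 and 8.86. Kif23, a mitotic kinesin, measured 8.54, 3.83 and 6.77 FPKM and 10.3, 11.3 and 9.60, with every KO library above every control. Slbp, which binds histone mRNA in S phase, measured 12.4 ± 1.32 FPKM in the controls and 20.9 ± 0.686 in the KO cells, and Dtl 2.19 ± 0.425 and 6.39 ± 2.06. The log2 difference of Kif23 was 0.68, and 0.25 without control 2 and 3. Without KO 1 and 3, that of Dtl was 0.67 against 1.18, and that of Mki67 0.31 against -1.11.

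Of 44 ribosomal protein genes, 42 had higher estimates, with a median of 0.39 (camera adjusted p = 2.48e-04, and adjusted p = 0.740 with an estimated correlation). The call was lost without control 1 (camera adjusted p = 0.0842) and without KO 2 (camera adjusted p = 0.262). The median was 0.59 without control 2, 0.25 without control 3, 0.60 without KO 1, 0.49 without control 2 and 3 and 0.64 without KO 1 and 3. Of 28 G2 and M phase genes, 24 had lower estimates, with a median of -0.44 (camera adjusted p = 0.00874, and adjusted p = 0.740 with an estimated correlation). The call was lost without control 3 (median -0.24, camera adjusted p = 0.107), KO 1 (median -0.28, camera adjusted p = 0.112) and KO 3 (median -0.01, camera adjusted p = 0.525). Without KO 1 and 3, where KO 2 was the only KO library, the direction reversed, with a median of 0.65. Without control 2 and 3, where control 1 was the only control, the median was -0.34. The median was -0.96 without KO 2 and -0.72 after quantile normalization. S phase genes did not pass (median 0.09, camera adjusted p = 0.448), but passed higher without KO 3 (median 0.36, camera adjusted p = 0.0190). Their median was -0.17 without KO 2, 0.24 without KO 1, -0.14 after quantile normalization and -0.10 without control 2 and 3. It was highest, 0.67, without KO 1 and 3, where KO 2 was the only KO library. In these 3 lists, 0 genes passed over all genes or adjusted over the list alone.

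Of the interferon-stimulated genes, Usp18 measured 2.73 ± 2.54 FPKM in the controls and 11.6 ± 4.35 in the KO cells, and Xaf1 2.47 ± 1.80 and 7.87 ± 2.47. In control 1, 2 and 3 Usp18 measured 5.66, 1.24 and 1.29 FPKM and Xaf1 4.56, 1.38 and 1.49. Their log2 differences of 1.89 and 1.43 were 0.85 and 0.63 without control 2 and 3, and 1.23 and 0.92 without KO 1 and 3. Of 32 members, 26 had higher estimates, and the list did not pass (median 0.62, camera adjusted p = 0.0728). Its median was 0.05 without KO 2 (camera adjusted p = 0.945), 0.24 without control 3, 0.39 without control 2, 0.35 after quantile normalization and -0.33 without control 2 and 3. Among fits with at least 2 libraries per group, camera passed it higher without control 1 (median 1.08, camera adjusted p = 0.00600), KO 1 (camera adjusted p = 0.00981) and KO 3 (camera adjusted p = 0.0187), and among protein-coding genes alone (camera adjusted p = 0.0118). Its median was also higher, 0.93, without KO 1 and 3, where KO 2 was the only KO library. Apoptosis and p53 targets (median -0.10, camera adjusted p = 0.148) did not pass, with a median of -0.22 without control 2, 0.03 without KO 3, -0.30 after quantile normalization, -0.28 without control 2 and 3 and 0.11 without KO 1 and 3. Cdkn1a of that list measured 59.6 ± 21.5 and 26.3 ± 8.35 FPKM, and the pro-apoptotic Bbc3 37.6 ± 24.0 and 115 ± 55.9, with log2 differences of -1.13 and 1.62, and of -0.59 and 0.67 without control 2 and 3. Heat shock genes (median 0.05, mean 0.01, camera direction lower, adjusted p = 0.776) and ribosome biogenesis and Myc targets (median and mean 0.00, camera direction lower, adjusted p = 0.781) did not pass. Bag3 measured 9.62 ± 1.46 and 5.64 ± 1.33 FPKM, and Wdr12 4.89 ± 1.37 and 8.99 ± 1.55. The heat shock median ranged from -0.11 without KO 2 to 0.19 without KO 3. Among fits with at least 2 libraries per group, camera passed ribosome biogenesis lower without control 3 (median -0.26, camera adjusted p = 0.0259) and KO 2 (median -0.23, camera adjusted p = 0.0494). The median of that list was 0.21 without control 1 and -0.12 after quantile normalization. With 1 library in a group it went both ways, to -0.37 without control 2 and 3 and 0.40 without KO 1 and 3. In these 4 lists, 0 genes passed over all genes or adjusted over the list alone.

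Neutrophil and erythroid markers had the largest median differences of the 31 lists tested, and the means of both lists were highest in control 2 and 3. S100a8 and S100a9, the abundant calcium-binding proteins of neutrophils, measured 109, 4503 and 7643 FPKM and 164, 8684 and 16130 FPKM in control 1, 2 and 3. In KO 1, 2 and 3 they measured 64.9, 20.2 and 170 FPKM and 100, 25.7 and 353 FPKM. Haemoglobin Hbb-bs measured 1.65, 999.9 and 484 FPKM in control 1, 2 and 3 and 1.52, 0.621 and 14.7 in KO 1, 2 and 3. The neutrophil collagenase Mmp8 measured 176 ± 81.0 FPKM in the controls and 21.1 ± 6.84 in the KO cells, with every KO library below every control. The macrophage genes Mpeg1 and Fcgr3 measured 284 ± 160 and 48.2 ± 14.0 FPKM and 209 ± 138 and 16.9 ± 5.47 FPKM, with log2 differences of -2.39 and -3.22, and of -1.30 and -1.55 without control 2 and 3.

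All 11 neutrophil markers tested had lower estimates in the KO libraries, with a median of -3.91 (camera adjusted p = 3.63e-07, and adjusted p = 0.639 with an estimated correlation). Their mean log2(FPKM + 1) was 3.64, 7.90 and 8.70 in control 1, 2 and 3 and 3.31, 1.80 and 4.01 in KO 1, 2 and 3. Of 10 erythroid and platelet markers, 9 had lower estimates, with a median of -1.93 (camera adjusted p = 0.00574, and adjusted p = 0.639 with an estimated correlation). All 15 macrophage and monocyte markers had lower estimates, with a median of -0.80 (camera adjusted p = 1.26e-04, and adjusted p = 0.639 with an estimated correlation). Without control 2 and 3, the medians were -0.51 for neutrophils, 0.05 for erythroid cells and platelets and -0.71 for macrophages and monocytes. The erythroid call was lost without control 2 (median -1.25, camera adjusted p = 0.0509) or KO 2 (camera adjusted p = 0.0930), and its median was -3.07 without control 1. The macrophage call was lost without KO 2 (median -0.41, camera adjusted p = 0.0831), and its median was -1.38 without KO 3 and -2.91 without KO 1 and 3. Adjusted over the list alone, 1 neutrophil marker (Mmp8) and 3 macrophage markers passed lower and 0 erythroid markers did, and over all genes 0 passed.

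All 11 B cell markers tested had higher estimates in the KO libraries, with a median of 1.12 (camera adjusted p = 0.00198, and adjusted p = 0.653 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. Ighm measured 204, 56.1 and 68.9 FPKM in control 1, 2 and 3 and 396, 289 and 314 in KO 1, 2 and 3, a log2 difference of 1.82, and 0.69 without control 2 and 3. Without control 2 and 3 the B cell median was -0.07, while camera's direction stayed higher. The B cell median was 0.45 without KO 1 and 3 and 1.82 without control 1. Plasma cell (median -0.74, camera adjusted p = 0.235), NK and innate T cell (median 0.16, mean -0.01, camera direction lower, adjusted p = 0.866) and dendritic cell markers (median 0.37, camera adjusted p = 0.431) did not pass, with 0 members past the threshold over all genes or adjusted over the list alone. camera passed plasma cell markers lower without KO 2 (median -1.96, camera adjusted p = 0.0153), while their median was 0.14 without control 1. With 1 library in a group, the median was lower still, -2.88, without control 2 and 3, where control 1 was the only control, and 1.04 without KO 1 and 3. Among fits with at least 2 libraries per group, camera passed dendritic cell markers higher without control 1 (median 0.82, camera adjusted p = 0.0287). Their median was -0.02 without control 3 and 0.21 after quantile normalization. Without control 2 and 3, where control 1 was the only control, the direction was the opposite, with a median of -0.46. The NK median was 0.43 without control 1, 0.54 without control 3, 0.46 without KO 1, -0.69 without control 2, -0.11 after quantile normalization and -0.44 without control 2 and 3. Stroma and endothelium had 3 tested members, too few for the test, with Pecam1 at 19.3 ± 3.38 and 22.9 ± 11.3 FPKM.

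**Figure D3:**
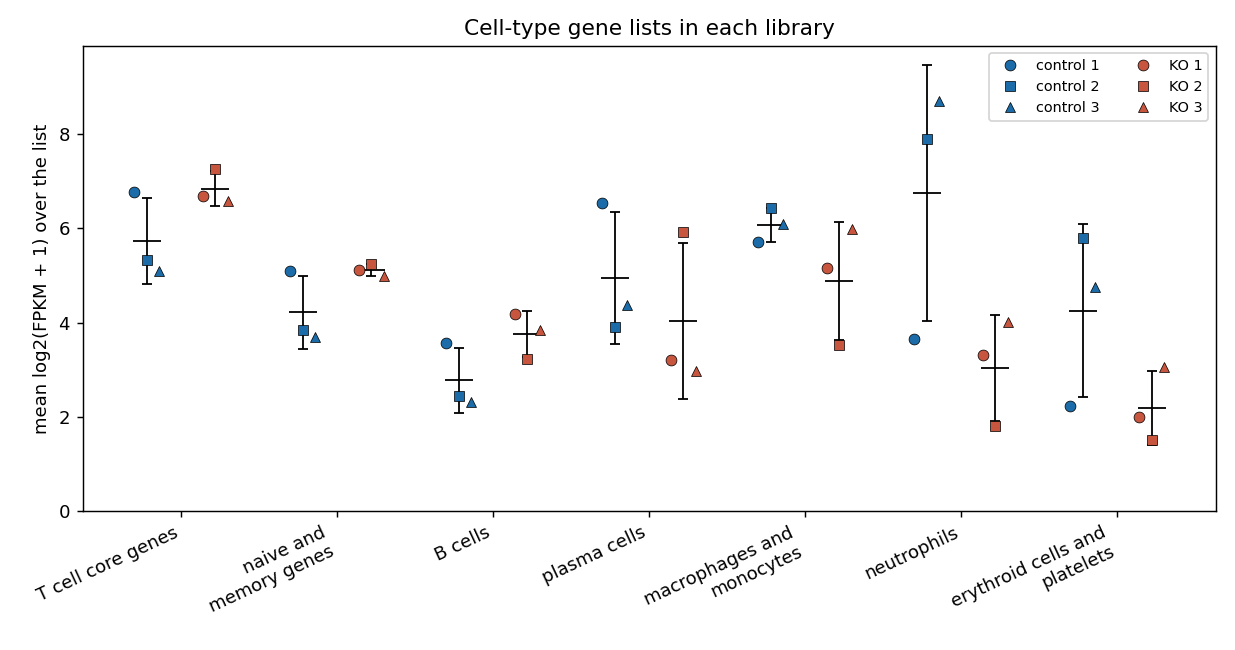
Mean log2(FPKM + 1) of 7 fixed cell-type lists (y axis) in each library, with group mean and SD as bars. Control 1 lies beside the KO libraries for T cell core genes (6.77 against 6.58 to 7.26) and neutrophil markers (3.64 against 1.80 to 4.01), while control 2 and 3 lie at 5.34 and 5.09 and at 7.90 and 8.70.

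Xist and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty separated the groups completely. Xist, the RNA that silences an X chromosome in female cells, measured 19.8, 21.97 and 40.5 FPKM in control 1, 2 and 3 and 0.473, 0.262 and 0.0929 in KO 1, 2 and 3, and its log2 difference was -4.42 (SE 0.36, limma adjusted p = 0.151). The Y-linked Ddx3y measured 1.82, 0.166 and 0 FPKM in the controls and 29.5, 20.6 and 19.7 in KO 1, 2 and 3, and Eif2s3y 2.17, 0.208 and 0.0160 FPKM and 25.2, 30.5 and 20.9. The Y-linked gene model Gm47283 overlapped, at 33.1, 7.40 and 3.96 FPKM and 20.8, 14.1 and 19.5. These genes were chosen after their values were seen. Genotype and this difference could not be separated in any gene or list above, since every control library had more Xist and less Ddx3y than every KO library.

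In 14 of 31 lists camera's adjusted p was under 0.05 at its preset correlation, 4 higher and 10 lower, and in 0 with an estimated correlation. fry, which tests whether genes of a list move on balance in 1 direction, passed 0 lists. Its mixed test, for changes in either direction, gave adjusted p under the threshold for the hypoxia response (0.0123) and the hexose transporters (0.0178). The medians of the 14 lists lay on the same side of the median of all genes before and after quantile normalization.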

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

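The fits without control 2 and 3, without KO 1 and 3, with a neutrophil covariate, on protein-coding genes alone and by limma-voom were chosen after the results were seen. A log2 threshold of 1 selects among genes already called, so its count of 0 was fixed in advance. Fits that leave 1 library in a group are not among the gene counts here. They are part of the totals of 1130 gene values and 401 list values below. The count of 0 genes past limma's threshold held with a pseudocount of 0.1, no filter (35085 genes), quantile normalization and no antigen receptor segments. It also held with the neutrophil covariate, on protein-coding genes alone and by limma-voom. With the replicate number as a block it was also 0, and the block moved the list count from 14 to 15, the added list being the mitochondrially encoded genes (lower, camera adjusted p = 0.0301). Numbers are not shown to pair the samples: same-numbered libraries deviated together with correlations of 0.11, 0.02 and 0.02, and only control 1 correlated best with its own number. With 1 library left out, the gene count ranged from 0 to 1821, at 363 without control 1 and 1821 without KO 2, and the cause was not tested. Over these fits the count of lists ranged from 12 to 16, with camera at its preset correlation. An estimated correlation was not used in any of them, so lists that passed there lack that check. The list count fell to 0 with an estimated correlation and 0 with fry, both of which allow for genes of a list varying together, and to 9 without control 2 and 3, where control 1 was the only control and was assumed to vary like the KO libraries, as KO 2 was like the controls without KO 1 and 3. Without KO 1 and 3, glycolysis turned to a median of 0.30, amino acid transport and one-carbon metabolism to 0.25 and G2 and M phase to 0.65, and without control 2 and 3 the erythroid and platelet list turned to 0.049; the cause was not tested. The log2 difference of Slc2a10 was -0.62 with a pseudocount of 0.1, which magnifies values near 0, and -0.13 without control 2 and 3, and with 1 library left out it ranged from -0.09 to -0.05. Of 1130 values of named genes across settings, 1053 kept their direction and stayed on the same side of the threshold. A further 56 newly passed it, 29 of them without KO 2 and 27 without control 1. The other 21, which had not passed, changed direction, 6 of them without KO 1 and 3 and 5 without control 2 and 3. As 0 named genes passed in the main fit, the same side means only that a gene was still not called. With no filter, the replicate block, no antigen receptor segments and protein-coding genes alone, the log2 difference of a gene cannot change. The directions of 76, 76, 72 and 70 of these values were thus fixed in advance. Of 401 list values, 280 kept both, 55 lost the call and 24 gained it. Another 38 that had not passed changed direction, 9 of them without KO 1 and 3 and 4 without control 2 and 3. The 4 that had passed and turned came only from these fits, 3 without KO 1 and 3 and 1 without control 2 and 3. Size factors, upper-quartile factors, DESeq2, voom with quality weights and both count filters were planned for counts and not run, because the values were FPKM. KO 1 and KO 3 held the fewest reads, so a gene of 1 kb near 1 FPKM rests on about 3 reads there.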

Other observations

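Apart from the tests of shallow depth and of unspliced RNA in KO 1 and KO 3, the tests below were chosen after the results they concern were seen, as were the genes and segments named in the first 2 paragraphs. Plasma cell transcripts were highest in 1 library of each group. The immunoglobulin light chain Igkc measured 3921 FPKM in control 1 and 2764 in KO 2, against 440 and 794 in control 2 and 3 and 287 and 394 in KO 1 and 3. Jchain, which joins secreted immunoglobulin units, measured 225 FPKM in control 1 and 154 in KO 2, and between 4.76 and 38.3 in the other 4 libraries. The 245 immunoglobulin V segments summed to 7251 and 3266 FPKM in control 1 and KO 2 and to between 400 and 717 in the others.

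T cell receptor beta segments were spread over many V genes in every library, with the most abundant of 28 Trbv segments at 9.71% to 11.8% of their summed FPKM. Among 101 Trav segments the most abundant held 5.40% to 5.73% in the controls and KO 2, but Trav4-1 held 13.9% in KO 1 and Trav9n-1 15.95% in KO 3, the libraries with the fewest reads. Ifng, the main cytokine of CD8+ effector cells, measured 11.7 and 15.4 FPKM in KO 1 and KO 3, 0.473 in KO 2 and 1.70, 0.720 and 0.770 in control 1, 2 and 3. KO 1 and KO 3 also had signal in many other gene models, such as Ndufb2 at 12.1 and 13.1 FPKM against 0.811 in KO 2. Whether Ifng has the same source was not tested. The myeloid receptors Fpr1 and Cd300lf, chosen after their values were seen, measured 36.1 ± 19.5 and 35.0 ± 20.1 FPKM in the controls and 4.02 ± 0.610 and 2.71 ± 1.16 in the KO libraries, without passing limma's threshold (limma adjusted p = 0.417 for both). Their log2 differences were -1.75 and -1.89 without control 2 and 3, against -2.73 and -3.11 with all libraries.

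Control 1 had Xist at 19.8 FPKM and also more Y-linked RNA than the other controls. As a share of the KO mean, its level was 7.83% for Ddx3y, 8.52% for Eif2s3y, 7.26% for Kdm5d and 13% for Uty, against at most 0.816% for these genes in control 2 and 3.

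The real split of the 6 libraries into 3 against 3 gave 0 genes past limma's threshold, and the highest of the others also gave 0. A count of 0 is matched by all 10 splits whatever they give, so this comparison shows nothing, and with 10 splits no share under 0.05 can be reached.

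The lists of T cell core and naive genes had higher medians, and those of neutrophil and erythroid genes lower ones, in the KO libraries, with camera's adjusted p at 0.639 for each with an estimated correlation. Library depth is argued against, since KO 2, at nearly the depth of control 2 and 3, exceeded their mean T cell core level by 2.05 on the log2 scale. RNA of non-T cells in control 2 and 3 may account for the pattern: the T cell core mean of control 1 differed from the KO mean by -0.078, control 1 lay within the KO range for the means of the T cell core and neutrophil lists, and control 2 and 3 outside both, although 7 of 18 T cell core genes and 3 of 11 neutrophil markers separated control 1 too (Mmp8 at 96.96 against 14.3 to 28.0 FPKM). All 12 neutrophil markers reached 1 FPKM in control 2 and 3, 11 did in control 1 and 10, 6 and 9 in KO 1, 2 and 3, with S100a9 at 164, 8684 and 16130 FPKM in control 1, 2 and 3 and 100, 25.7 and 353 in KO 1, 2 and 3, although the CD8+ collection named in the labels would remove neutrophils. An effect of the Glut10 deletion cannot be told apart from this, because control 1 lay 1.55 above the mean of control 2 and 3 and a single library, itself with Y-linked RNA that may come from another sample (Uty at 13% of the KO mean), cannot show which control is the exception.

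Many gene models had signal in KO 1 and KO 3. Shallow depth is argued against, since after thinning the lower of the 2 stood 15.6 percentage points above the highest other library in gene models with a read. Unspliced RNA alone is argued against, since the share of low noncoding models over 10 kb from expressed genes was 2.79 times that of the highest other library, more than the 1.63 times inside expressed genes. Genomic DNA in KO 1 and KO 3 may be a source: sensory receptor genes with a read stood 37.5 percentage points above the highest other library, although T cells are not known to transcribe these genes. KO 2 shares the genotype and had the lowest share, 10.2%, and no biological explanation was tested.

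Pdk1 was about the same in the 3 controls and higher in each KO library, and its log2 difference ranged from 1.82 to 2.28 over the settings run, with limma adjusted p from 0.00418 to 0.997. RNA of non-T cells in control 2 and 3 is argued against, as Pdk1 varied by 0.15 over the controls on the log2 scale where the T cell core mean varied by 1.68. Genomic DNA in KO 1 and KO 3 is argued against, as Pdk1 in KO 2 was 5.19 times the highest control. Sex of the mice cannot be told apart from genotype, since 0 libraries had an Xist and Ddx3y order against the rest of their group. A change with the Glut10 deletion, a difference between the sexes and another difference between the mice were not told apart by any test here, as libraries of both genotypes from 1 sex would be needed.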
